A study of Homo sapiens with 15 samples.

How the data were processed

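The series measured RNA in platelets of patients admitted with alcohol-associated hepatitis (AH), an acute inflammatory liver failure that follows heavy drinking, and of healthy donors. There were 15 libraries, 8 from AH and 7 from healthy donors, each from a separate person per the labels. They came in 2 batches, with 3 AH and 4 healthy libraries in batch 1 and 5 AH and 3 healthy libraries in batch 2, and each batch had its own deposited table. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a Clontech pico-input mammalian total RNA kit, which primes total RNA, so that nuclear, cytoplasmic and mitochondrial RNA can all be read. The submitters' processing notes name HISAT2, Picard and the GRCh38 build, without versions. The read counter, its annotation, its handling of strand and of reads that map to several places are not given in the sources used here.

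The deposited values are whole-number counts per gene, which the authors left unnormalised. Columns were matched to samples through the library name in the labels. Both tables list 58288 genes, of which 58025 carry an identifier of GENCODE release 29 on GRCh38 (55619 with the same version), and gene symbols and coordinates were taken from there. Of the 58288 genes, 564 that bear on a person's sex were left out of the tests, of the library sizes used in them and of the results by gene. Total counts per library, and the totals behind percent shares of all counts, still included them. In all 15 libraries more genes had a count of 2 than a count of 1, so both mates of a read pair may have been counted, and counts may then overstate the number of independent fragments. Without known strand handling, reads of a gene and of an antisense or overlapping partner cannot be separated.

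Total counts ran from 24.2 M to 55.7 M per library (median 36.9 M), of which 8.3 M to 27.7 M fell on nuclear protein-coding genes. The 105 pairs of libraries were compared for a library deposited more than once. The lowest chi-square per degree of freedom was 78.5, far above sampling noise, so each library was counted once.

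Genes with enough counts were kept with filterByExpr (12800 genes), scaled with TMM (factors 0.587 to 1.24) and tested in R 4.3.3 with edgeR 4.0.16's quasi-likelihood test, with batch and group as terms, two-sided, and Benjamini-Hochberg adjustment at a threshold of 0.05 over all genes tested. Fold changes are log2 values of AH over healthy with their standard errors (SE). CPM values are scaled by TMM and given as mean ± SD. The same test was run within each batch and for the group by batch interaction. The fit was tested on simulated data with 200 genes changed by known folds. With both batches it recovered 3.0% of genes changed 1.5-fold, 34.3% of genes changed 2-fold and 74.2% of genes changed 4-fold among 12800 genes, with 1.3% false calls. That simulation gave 75 calls against 2190 in the real data, where the adjustment is therefore less strict, so its recovery may be too low for the real data. Batch 1 alone recovered 25.8% of genes changed 4-fold among 13672 genes, batch 2 alone 39.4% among 13450 genes, and the interaction test 19.7% among 12800 genes.

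The 28 gene lists, of which the erythroid and glycolysis lists share BPGM, were fixed before the data were examined, as were the main tests, most alternatives and the naming rule. Lists with at least 5 tested genes (27) were tested with limma 3.58.1's camera on log2 CPM (prior count 2) at its preset correlation of 0.01, again with an estimated correlation, and with fry. Counts of list members are given after adjustment over all genes tested and, in parentheses, adjusted over the list alone. Shares of counts and mean marker levels were compared with exact two-sided permutation tests in which labels were exchanged within batches (1960 relabelings, smallest p 0.00051), adjusted over 13 measures. The mitochondrial rRNA share among them was not in the plan. The genes named are S100A9, S100A8 and S100A12, the 12 largest rises and 12 largest falls among called genes with a mean of at least 10 CPM and the same sign in both batches, and up to 4 members of each list with the smallest p. One gene that this rule selects is not reported here. Other members named beside their list were chosen after their values were seen. Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, other covariates, each batch alone and each library left out. After seeing the data, 5 were added: GC and length offsets, nuclear protein-coding genes only, leaving out libraries that stood apart in 2 ways, and an erythroid covariate. Plots were drawn with matplotlib from the tables.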

Results

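Platelets carry no nucleus, and their RNA is inherited from megakaryocytes or taken up in blood. The series asks how platelet RNA differs between patients hospitalised with alcohol-associated hepatitis (AH) and healthy donors, and its title singles out S100A9, a calcium-binding alarmin of myeloid cells, and injury of the endothelium. Counts per gene were available for 8 AH and 7 healthy libraries, with totals of 24.2 M to 46.8 M per library in AH and 29.6 M to 55.7 M in healthy donors. Between 15225 and 21141 genes had a count. With batch means removed, the groups differed along the first principal component, which held 22.5% of the remaining variance. The exact permutation p within batches was 0.00051, the smallest that 1960 relabelings can give. Without that removal, the first component parted the groups within each batch, but across batches they overlapped.

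The genes that rose most in AH, among called genes averaging at least 10 CPM with the same sign in both batches, included IFITM3, IGFBP2, MMP1, IFITM2 and COL6A3. IFITM3 (chromosome 11, 319669 to 327537), an interferon-induced restriction factor for enveloped viruses, was 13.3-fold higher (log2 fold change 3.73, SE 0.40, adjusted p = 9.0e-05), at 135 ± 100 CPM (SD, n = 8) against 11.5 ± 4.97 (n = 7). Its neighbour IFITM2 rose 8.1-fold, from 20.7 ± 6.64 to 152 ± 64.9 CPM (log2 fold change 3.02, SE 0.28). Both lay higher in all 8 AH libraries than in any healthy one, and because the IFITM genes are near-identical in sequence, the split of reads between them is uncertain. IGFBP2, an insulin-like growth factor binding protein, rose 14.7-fold (SE 0.62 on the log2 scale, adjusted p = 0.000845). MMP1, the interstitial collagenase, rose 11.1-fold, from 1.72 ± 1.33 to 24.8 ± 18.7 CPM. COL6A3, a chain of collagen VI, rose 7.0-fold, from 14.1 ± 8.09 to 116 ± 54.9 CPM. E2F1, a cell cycle transcription factor, and CTSW, a cysteine protease of the cathepsin family, rose by 3.06 (SE 0.34) and 3.12 (SE 0.36) on the log2 scale, and KLHDC8B by 2.81 (SE 0.46). The largest fold of this set belonged to MUSTN1, a musculoskeletal nuclear protein gene (4.09, SE 1.13), whose AH libraries spread widely (23.1 ± 29 CPM), as did those of WFDC1 (18.0 ± 30.5 CPM, log2 fold change 3.05, SE 0.85), and each of these 2 calls was lost in 3 of 15 fits that left out 1 library. ALAS2 and CA1 complete the 12 largest rises and are given with the erythroid genes.

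In all, 1226 genes were higher and 964 lower in AH among 12800 tested, or 17.1% together, and 598 of the higher and 280 of the lower genes differed at least 2-fold. The higher share of these calls, 56%, changed with the setting: with library sizes alone, 1144 genes were higher and 542 lower (67.9% higher), and with GC and length offsets 925 were higher and 1074 lower (46.3% higher). Genes with a higher level in AH were richer in GC (median 55.1% of the transcript) than genes with a lower level (41.6%), against 47.5% over all tested genes, and with the offsets 1308 of the 2190 genes were called again with the same sign, while 26 changed sign. Spearman's rho between fold change and GC went from 0.314 to -0.14 with the offsets, so they removed more than the trend. A call of a GC-rich gene that ended with the offsets is therefore not shown to be due to GC.

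**Figure D1:**
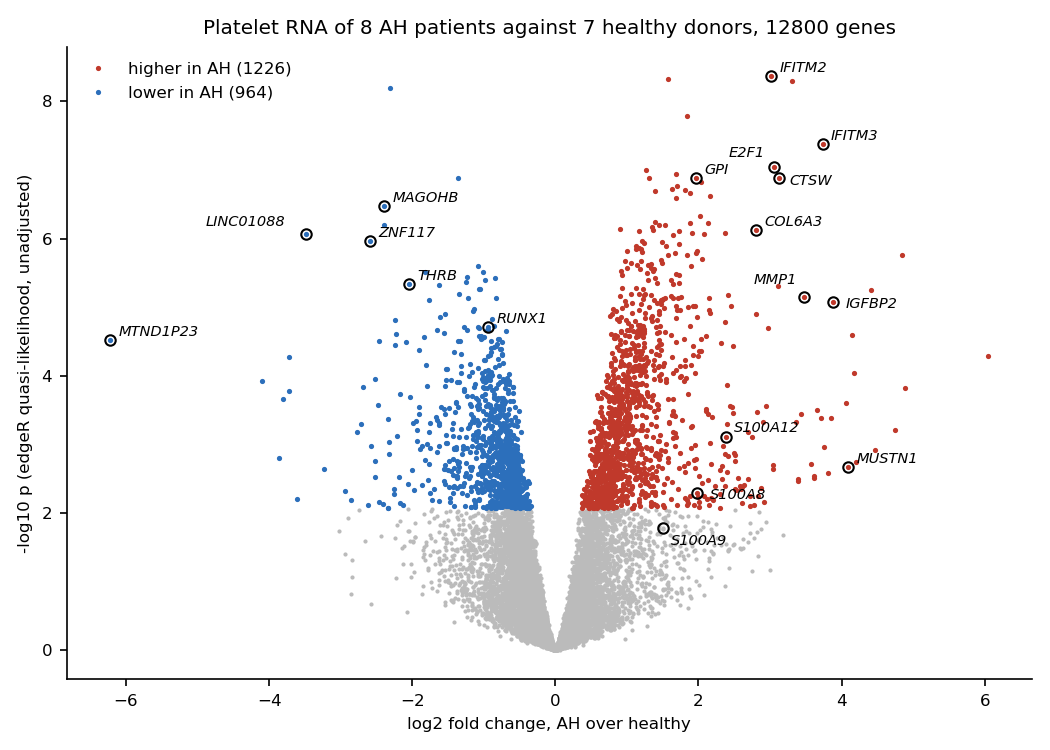
Log2 fold change of AH over healthy (horizontal axis) against the unadjusted p on a -log10 scale (vertical axis) for 12800 genes, with 1226 higher genes in red, 964 lower genes in blue and the others in grey. IFITM2 and IFITM3 lie at the top right, whereas S100A9 lies below the called genes.

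Of the 12 genes that fell most, 4 were nuclear copies of mitochondrial sequence and several were noncoding. LINC01088 (chromosome 4, 78971748 to 79308798) fell by 3.48 on the log2 scale (SE 0.46), from 45.6 ± 34.5 CPM in healthy donors to 4.12 ± 1.97 in AH, and was lower in all 8 AH libraries than in any healthy one. LINC02569 fell by 2.69 (SE 0.55) and C15orf54 by 2.52 (SE 0.50). Protein-coding genes of this set were ZNF117, a zinc finger gene (fell by 2.59, SE 0.35), MAGOHB, an exon junction complex subunit (fell by 2.39, SE 0.30), THRB, a thyroid hormone receptor (fell by 2.04, SE 0.31), LAMP5, a lysosome-associated membrane protein (fell by 1.86, SE 0.47), and NOMO1 (fell by 2.21, SE 0.54), which shares reads with near-identical paralogs. MTND1P23 (log2 fold change -6.22, SE 1.10), MTND2P28 (-3.72, SE 0.70), MTRNR2L8 (-2.57, SE 0.65) and MTND4P12 (-2.06, SE 0.61) are nuclear copies of mitochondrial sequence, so their values are uncertain. Leaving out 1 library ended the call of MTND4P12 in 4 of 15 fits and that of MTRNR2L8 in 1, and MTND4P12 had an adjusted p of 0.0506 with GC and length offsets. These copies moved in the same direction as the mitochondrial RNAs described further on.

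S100A9 itself (chromosome 1, 153357854 to 153361027) averaged 95.8 ± 86.2 CPM in AH (n = 8) and 34.1 ± 13.1 in healthy donors (n = 7), a log2 fold change of 1.502 (SE 0.564) that did not pass the threshold (adjusted p = 0.0775, exact permutation p = 0.0893). It was above all healthy libraries in 5 of 8 AH libraries, and the log2 fold change was 0.85 (SE 0.42) in batch 1 and 2.20 (SE 0.87) in batch 2. It passed when either of 2 AH libraries, 1 in each batch, was left out (adjusted p 0.0391 and 0.0325). Its heterodimer partner S100A8 rose 3.94-fold, from 17.6 ± 7.11 to 73.1 ± 79.0 CPM (adjusted p = 0.0351, or 0.0551 with GC and length offsets, and lost in 5 of 15 fits that left out 1 library), and S100A12, another myeloid alarmin, rose 5.20-fold from 1.14 ± 0.743 to 5.45 ± 4.42 CPM (adjusted p = 0.0108). Of 11 tested S100 family genes, 3 rose, the third being S100A13, and 8 did not pass (5 rose adjusted over the list alone). S100A10, the annexin A2 partner, had a log2 fold change of 0.88 (SE 0.31, adjusted p = 0.0637). The list stood above other genes (camera adjusted p = 0.0126), but not with an estimated correlation (adjusted p = 0.359), nor without 1 healthy library of batch 2 (adjusted p = 0.0664).

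Some transcripts for neutrophil granule proteins rose as well. All 13 tested members had positive fold changes (median log2 fold change 2.72, 1.79 in batch 1 and 3.04 in batch 2), and 5 rose (12 adjusted over the list alone). DEFA4, a defensin of early granules, averaged 1.54 ± 2.33 CPM in AH and 0.0442 ± 0.0762 in healthy donors, and MPO, the myeloperoxidase, 4.96 ± 6.65 and 0.542 ± 0.394. MMP8 and ARG1 rose by 4.21 (SE 1.13) and 2.84 (SE 0.89) on the log2 scale. The ARG1 call was lost in 8 and the MPO call in 7 of 15 fits that left out 1 library, and MPO did not pass with GC and length offsets (2.18, SE 0.88, adjusted p = 0.1004). Camera gave an adjusted p of 4.5e-06, and the adjusted p was 0.293 with an estimated correlation. Markers of mature neutrophils did not follow. None of 15 passed either over all genes or adjusted over the list alone, with ALPL at a log2 fold change of 1.497 (SE 0.660, adjusted p = 0.130), CMTM2 at 0.40 (SE 0.23), PROK2 at -0.92 (SE 0.56) and AQP9 at 0.76 (SE 0.48). Their mean log2 CPM was 0.156 ± 0.769 in AH and 0.0638 ± 0.616 in healthy donors (exact permutation p = 0.705). None of 18 monocyte markers passed (0 adjusted over the list alone): CYBB had a log2 fold change of 0.46 (SE 0.16, adjusted p = 0.0554), CD163 1.03 (SE 0.52), LGALS2 -1.37 (SE 0.90) and CLEC7A -0.43 (SE 0.36). With GC and length offsets CYBB passed (0.66, SE 0.19, adjusted p = 0.0241).

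**Figure D2:**
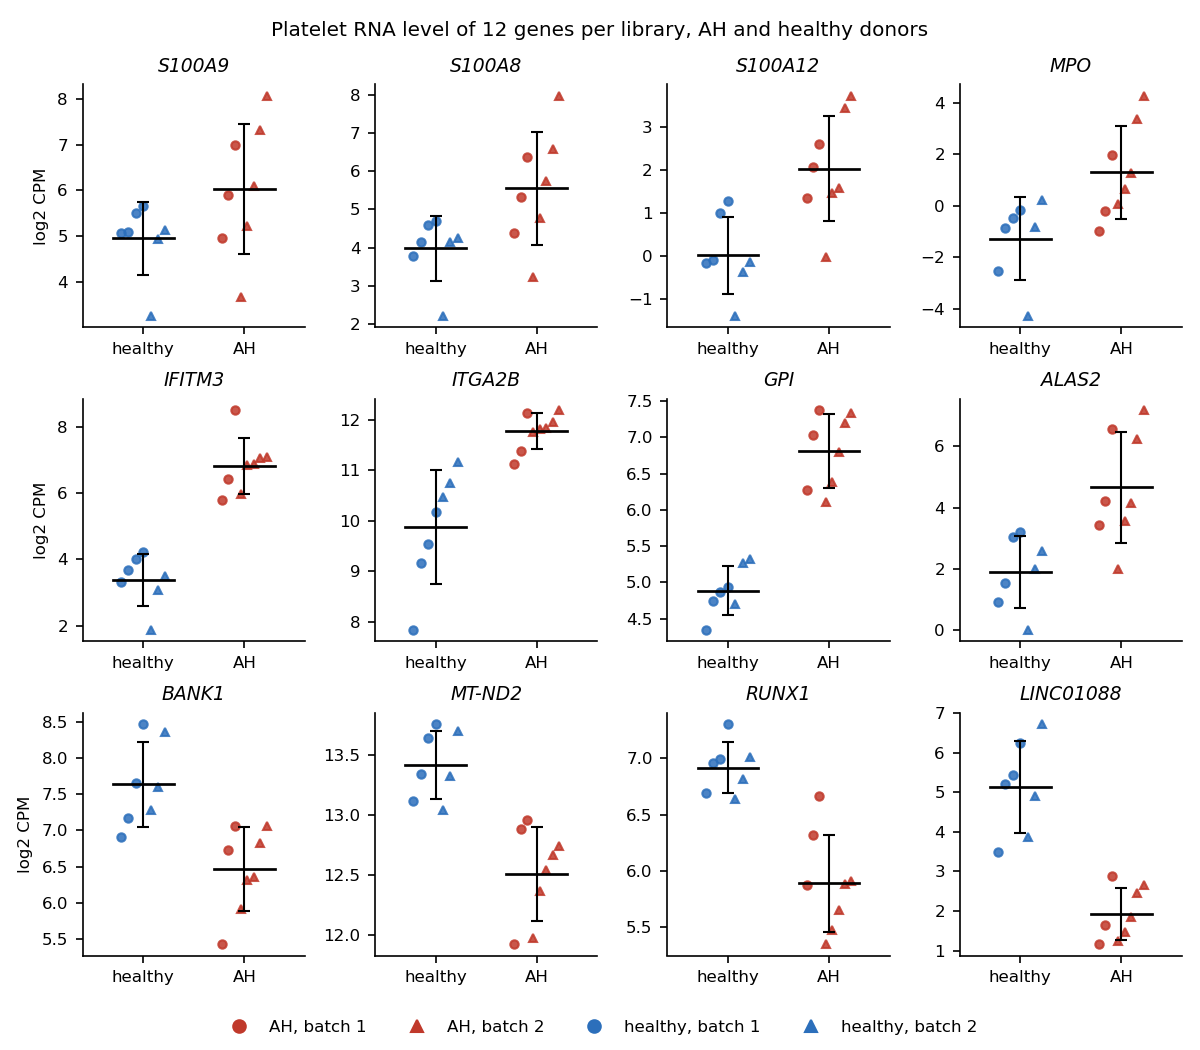
Log2 CPM of 12 genes per library (vertical axes, each with its own range) in healthy and AH donors, with circles for batch 1 and triangles for batch 2; lines and bars are the mean and SD over 7 healthy and 8 AH libraries. The groups overlap for S100A9 and S100A8 and are apart for IFITM3, GPI and LINC01088.

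The lists of platelet identity, granule cargo and activation genes stood above other genes by camera, though not with an estimated correlation. Most members of each did not pass. Of 27 platelet and megakaryocyte identity genes, 10 rose and 1 fell (16 and 1 adjusted over the list alone), with medians of 0.89 in batch 1 and 0.37 in batch 2. ITGA2B and ITGB3, the subunits of the fibrinogen receptor, rose 3.08-fold and 2.31-fold, to 3595 ± 836 and 5037 ± 893 CPM, and MYL9, a myosin light chain, and CMTM5 rose by 1.65 (SE 0.32) and 0.93 (SE 0.19) on the log2 scale. RGS18, a regulator of G protein signalling, fell by 1.016 (SE 0.280). PF4 and PPBP, the abundant platelet chemokines, did not pass (0.11, SE 0.24, and -0.31, SE 0.28). Camera gave an adjusted p of 1.6e-05 for the list and 0.363 with an estimated correlation. The mean log2 CPM of these markers was 8.93 ± 0.213 in AH and 8.28 ± 0.631 in healthy donors (exact permutation p = 0.00867, adjusted p = 0.0282). In healthy donors it was 7.90 in batch 1, where mitochondrial rRNA averaged 44.8% of counts, and 8.79 in batch 2, where it averaged 24.6%. Of 26 granule cargo genes, 8 rose and none fell (11 rose and 2 fell adjusted over the list alone; medians 0.63 in batch 1 and 0.34 in batch 2), among them TIMP1, an inhibitor of metalloproteinases (log2 fold change 1.17, SE 0.18), SPARC (0.89, SE 0.20), APP (0.79, SE 0.16) and APLP2 (0.61, SE 0.15). Camera gave an adjusted p of 0.00162, and the adjusted p was 0.387 with an estimated correlation. Of 30 activation receptor and signalling genes, 12 rose and none fell (15 rose and 1 fell adjusted over the list alone; medians 0.56 in batch 1 and 0.34 in batch 2), including FCGR2A, the platelet Fc receptor (1.83, SE 0.26), FCER1G, the signalling partner of the collagen receptor GP6 (1.17, SE 0.23), GNAI2 (0.80, SE 0.13) and the calcium sensor STIM1 (1.00, SE 0.20). This list had a camera adjusted p of 0.000337, and an adjusted p of 0.358 with an estimated correlation. With GC and length offsets the medians of these 3 lists were smaller, at 0.28 against 0.56 for identity, 0.23 against 0.44 for cargo and 0.20 against 0.45 for activation genes, and 7, 9 and 7 of their members rose. CMTM5 became 0.55 (SE 0.16), GNAI2 0.40 (SE 0.13) and STIM1 0.60 (SE 0.16).

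The actin cytoskeleton list had the most members called for its size among the platelet lists. Of 24 genes, 17 rose and none fell (17 adjusted over the list alone), with a median log2 fold change of 0.86 (1.20 in batch 1 and 0.73 in batch 2). With GC and length offsets 14 rose and 1 fell, and the median was 0.59. ARPC1B, a subunit of the branching complex Arp2/3, rose 2.89-fold to 1185 ± 278 CPM, CFL1, the severing protein cofilin, 2.62-fold to 676 ± 144 CPM, and CAPZB and MYL6 rose 2.25-fold and 2.11-fold. The camera adjusted p was 1.0e-10, and the adjusted p was 0.190 with an estimated correlation. Granule secretion genes went both ways. Of 23, 4 rose and 1 fell, as they did adjusted over the list alone: NBEAL2, whose loss causes gray platelet syndrome, rose by 1.38 (SE 0.20), HPS1 by 1.06 (SE 0.17) and UNC13D by 1.12 (SE 0.21), and HPS4 fell by 0.62 (SE 0.16), a call lost in 1 of 15 fits with 1 library left out. The 3 rises were smaller with GC and length offsets: NBEAL2 0.80 (SE 0.17), HPS1 0.56 (SE 0.14) and UNC13D 0.52 (SE 0.14). The list's median was -0.07 and its mean 0.12, and it did not pass (camera adjusted p = 0.473). Among 18 megakaryocyte transcription factors, RUNX1 fell by 0.94 (SE 0.16), from 122 ± 19.9 to 61.7 ± 20.0 CPM, whereas GATA1 and LYL1 rose by 0.92 (SE 0.20) and 0.85 (SE 0.18); 2 rose and 3 fell adjusted over the list alone. With GC and length offsets RUNX1 still fell and the calls of GATA1 and LYL1 ended (GATA1 0.50, SE 0.17, adjusted p = 0.058, and LYL1 0.50, SE 0.16, adjusted p = 0.0501). The list did not pass (camera adjusted p = 0.624).

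The IFITM rise did not extend to the interferon-stimulated genes as a list. Of 35 tested, 6 rose and none fell (6 adjusted over the list alone): IFITM1, IFITM2, IFITM3, RSAD2, LY6E (log2 fold change 1.24, SE 0.27) and IFI6 (2.40, SE 0.56). LY6E did not pass with GC and length offsets (0.70, SE 0.29, adjusted p = 0.104). MX1, a classical interferon-induced GTPase, had a log2 fold change of 0.00 (SE 0.56) and ISG15, a ubiquitin-like modifier, 0.38 (SE 0.64). The list's median was 0.10 (-0.36 in batch 1 and 0.57 in batch 2) and camera gave an adjusted p of 0.105. Of 24 innate inflammatory signalling genes, 3 rose (0 adjusted over the list alone), namely the kinase IRAK1 (0.66, SE 0.18), CASP4, a sensor caspase for lipopolysaccharide (0.46, SE 0.15), and SOCS3, a cytokine signalling suppressor (1.42, SE 0.47). The calls of IRAK1 (0.03, SE 0.19, adjusted p = 0.935) and SOCS3 (0.91, SE 0.49, adjusted p = 0.223) ended with GC and length offsets. With 1 library left out SOCS3 lost its call in 8 and CASP4 in 4 of 15 fits. NFKB1 had -0.35 (SE 0.21), and the list did not pass (camera adjusted p = 0.739).

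Genes for factors that act on the endothelium and in the plasma cascades were partly higher. Of 19 angiogenic and endothelium-acting genes, 8 rose (8 adjusted over the list alone), with medians of 0.81 in batch 1 and 0.30 in batch 2. Those with the smallest p were MMP1, ENG, the TGF-beta coreceptor endoglin (log2 fold change 1.43, SE 0.31), and the growth factors FGF2 (1.20, SE 0.31) and VEGFB (1.07, SE 0.29). The camera adjusted p was 0.00146, and the adjusted p was 0.190 with an estimated correlation. With GC and length offsets the median of 0.37 became 0.17, 4 genes rose, and ENG (0.83, SE 0.30, adjusted p = 0.0683) and VEGFB (0.45, SE 0.27, adjusted p = 0.279) did not pass. VEGFB also lost its call in 1 of 15 fits with 1 library left out. Of 14 coagulation and complement genes, 5 rose (5 adjusted over the list alone), with medians of 0.53 in batch 1 and 0.31 in batch 2. SERPING1, the C1 inhibitor, rose 3.97-fold, from 7.18 ± 6.19 to 30.7 ± 25.9 CPM, with a log2 fold change of 3.80 (SE 0.48) in batch 1 and 0.55 (SE 0.65) in batch 2. The others had lower levels: C1QA and C1QB, subunits of complement C1q, averaged 1.18 ± 0.889 and 1.65 ± 1.22 CPM in AH against 0.223 ± 0.151 and 0.368 ± 0.286, F12 (coagulation factor XII) averaged 0.686 ± 0.255 against 0.121 ± 0.127, and CD59, a complement inhibitor, rose by 0.80 (SE 0.24) on the log2 scale. Neither F12 (adjusted p = 0.0538) nor C1QB (adjusted p = 0.079) passed with GC and length offsets. With 1 library left out the call was lost in 4 of 15 fits for C1QB and in 1 for CD59. Camera gave an adjusted p of 0.0121, but the adjusted p was 0.190 with an estimated correlation and 0.0538 without 1 healthy library of batch 2. Of 10 endothelial markers, EGFL7 (1.13, SE 0.20) and ESM1 (1.80, SE 0.51; call lost in 1 of 15 fits with 1 library left out) rose, the same 2 adjusted over the list alone, and TEK (1.83, SE 0.70) and STAB1 (1.31, SE 0.52) did not pass; the list had a median of 0.52 (0.32 in batch 1 and 0.82 in batch 2) and a camera adjusted p of 0.0798. EGFL7 became 0.49 (SE 0.16, adjusted p = 0.0482) with GC and length offsets, where 1 other member was called lower. With fry the endothelial list was higher (adjusted p = 0.0124), whereas camera with an estimated correlation gave an adjusted p of 0.275. Of the hepatocyte-secreted genes only ALB had enough counts to be tested, at 0.576 ± 0.348 CPM in AH and 0.0456 ± 0.0790 in healthy donors (log2 fold change 3.62, SE 1.04, adjusted p = 0.0247, with the same call adjusted over the list alone), and its call was lost in 2 of the 8 fits with 1 library left out in which it was tested.

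Many erythroid transcripts rose. Of 24 tested, 15 rose and none fell (19 adjusted over the list alone), with a median log2 fold change of 2.18 (1.45 in batch 1 and 2.88 in batch 2). ALAS2, which starts haem synthesis in red cell precursors, rose 10.3-fold, from 4.71 ± 3.17 to 47.4 ± 52.1 CPM, CA1, the red cell carbonic anhydrase, 8.66-fold, from 2.71 ± 0.861 to 30.5 ± 22.1 CPM, and AHSP, the alpha-globin chaperone, by 4.15 on the log2 scale (SE 0.72). ANK1 and DMTN, membrane skeleton genes, rose 2.62-fold and 2.22-fold, but with GC and length offsets, where 10 members rose, their log2 fold changes went from 1.39 to 0.89 and from 1.15 to 0.67. HBB averaged 1280 CPM in AH and 312 CPM in healthy donors (log2 fold change 2.00, SE 0.65). Haemoglobin genes together made up 0.312 ± 0.331% of counts in AH and 0.0582 ± 0.0380% in healthy donors, which did not pass (exact permutation p = 0.0714, adjusted p = 0.0844). By camera the adjusted p of the list was 1.0e-10, and the adjusted p was 0.190 with an estimated correlation. Of 19 iron and haem stress genes, 7 rose (7 adjusted over the list alone), including the glutathione peroxidases GPX4 (1.16, SE 0.16) and GPX1 (1.16, SE 0.25), the ferritin light chain FTL (0.96, SE 0.21) and the biliverdin reductase BLVRB (1.64, SE 0.39). GPX4 and GPX1 became 0.71 (SE 0.12) and 0.72 (SE 0.22) with GC and length offsets. Camera gave an adjusted p of 0.000256, and the adjusted p was 0.0807 with an estimated correlation.

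Some lymphocyte transcripts fell. Of 22 T and NK cell markers, 4 fell and none rose (4 fell adjusted over the list alone), among them LCK, the T cell receptor kinase (-0.99, SE 0.25), KLRB1 (-1.10, SE 0.27) and NKG7 (-0.74, SE 0.24). With 1 library left out, the NKG7 call was lost in 12 of 15 fits and the LCK call in 1. BCL11B had -1.04 (SE 0.42, adjusted p = 0.0956) and passed with GC and length offsets (-1.29, SE 0.41, adjusted p = 0.0419). The list's median was -0.65 (-0.81 in batch 1 and -0.45 in batch 2), with a camera adjusted p of 0.00196 and an adjusted p of 0.367 with an estimated correlation. Of 11 B and plasma cell markers, 4 fell and none rose (4 adjusted over the list alone): CD22 (-1.39, SE 0.30), BANK1 (-1.20, SE 0.28), TCL1A (-2.33, SE 0.58) and the B cell transcription factor PAX5 (-1.79, SE 0.45), whose call was lost in 1 of 15 such fits. In healthy donors BANK1 averaged 215 CPM, against 7.33 for CD22, 5.15 for TCL1A and 11.3 for PAX5. Whether its RNA came from the same cells as theirs was not tested. Of 12 immunoglobulin constant genes tested, 2 rose and 0 fell. The B and plasma cell list had a camera adjusted p of 0.00223, and an adjusted p of 0.346 with an estimated correlation. The mean marker levels themselves missed the threshold after adjustment (exact permutation p = 0.0286 for T and NK cells and 0.0332 for B cells, adjusted p = 0.0509 for both).

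**Figure D3:**
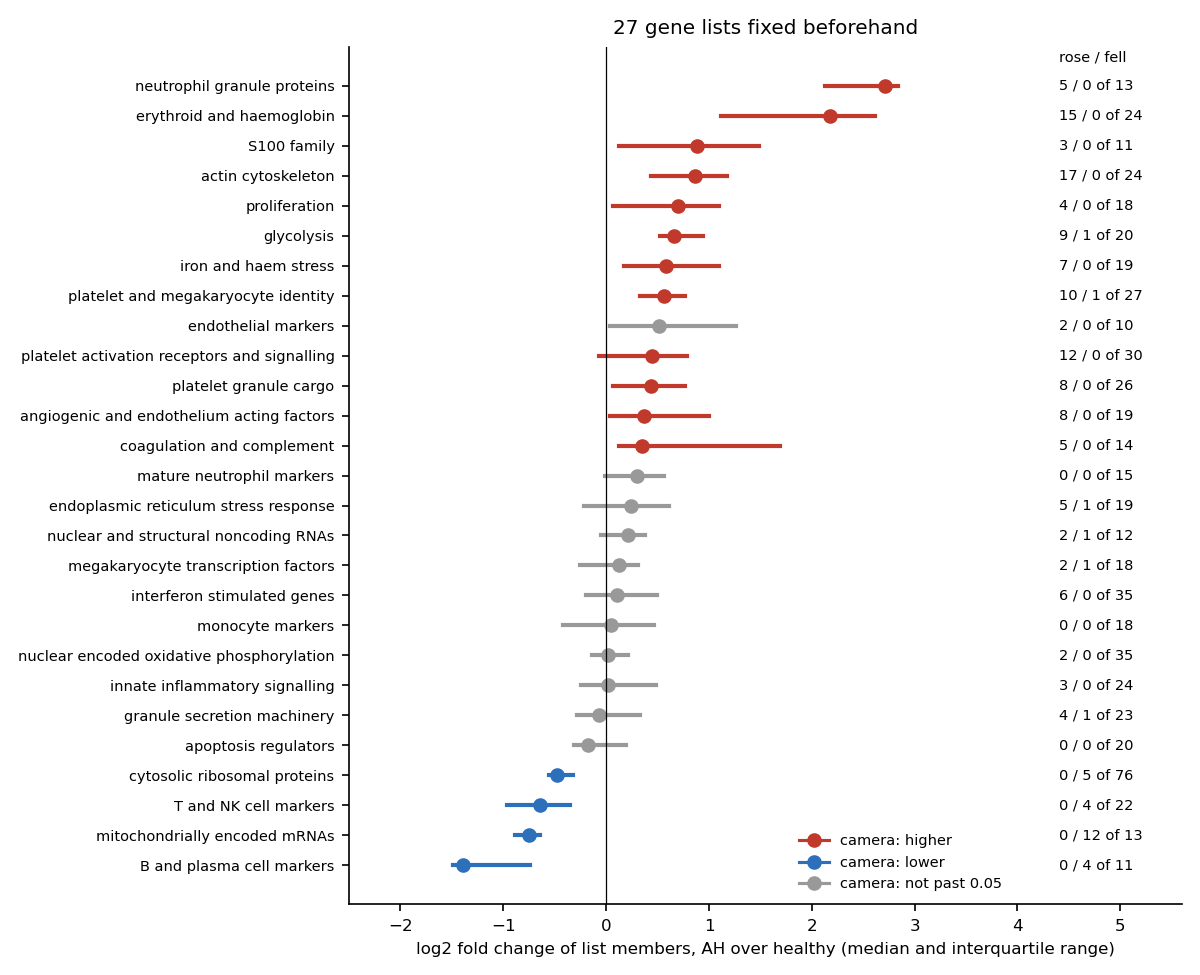
Median (points) and interquartile range (lines) of the log2 fold changes of the tested members of 27 gene lists, AH over healthy, with counts of members that rose or fell at the right; red and blue mark the 12 lists higher and 4 lists lower by camera with its preset correlation, whereas 0 passed with an estimated one. Neutrophil granule proteins (2.72) and erythroid genes (2.18) have the highest medians, and B and plasma cell markers (-1.39) the lowest.

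Most mitochondrially encoded mRNAs fell. Of the 13, 12 fell (12 adjusted over the list alone), with a median log2 fold change of -0.75 in AH: MT-ATP8 by -1.01 (SE 0.21), MT-ND1 by -0.91 (SE 0.20), MT-ND2 by -0.86 (SE 0.20) and MT-ATP6 by -0.83 (SE 0.19). MT-ATP8 did not pass with GC and length offsets (-0.43, SE 0.15, adjusted p = 0.065), when 9 of the 13 fell. Camera gave an adjusted p of 3.9e-07, and the adjusted p was 0.293 with an estimated correlation. As a share of counts these mRNAs made up 6.22 ± 0.798% in AH and 10.1 ± 2.81% in healthy donors (exact permutation p = 0.00204, adjusted p = 0.0133), and mitochondrial rRNA 16.1 ± 9.14% and 36.1 ± 14.8% (p = 0.0051 in the same permutation test, adjusted p = 0.0221). The 10 largest genes together took 44.5 ± 8.21% and 54.7 ± 10.6% (exact permutation p = 0.0423, adjusted p = 0.0551). Without mitochondrial genes the share of the 10 largest was instead higher in AH, by 7.07 percentage points (exact permutation p = 0.00306). The 35 nuclear genes of oxidative phosphorylation had a median of 0.02, and 2 rose, NDUFS5 (0.76, SE 0.23) and NDUFB9 (0.56, SE 0.17), but 0 adjusted over the list alone, and with 1 library left out these calls were lost in 3 and 4 of 15 fits; NDUFA2 (0.63, SE 0.23) and COX7C (-0.30, SE 0.14) did not pass, nor did the list (camera adjusted p = 0.557). Of 20 glycolysis genes, 9 rose and 1 fell (14 and 1 adjusted over the list alone). GPI, the second enzyme of the pathway, rose 3.89-fold from 30.2 ± 6.96 to 118 ± 39.0 CPM, above all healthy libraries in all 8 AH libraries, and ALDOA, ENO1 and PFKL rose 2.16-fold, 1.97-fold and 1.86-fold. With GC and length offsets the list's median of 0.66 became 0.42, and 5 genes rose and none fell. PFKL then did not pass (0.24 on the log2 scale, SE 0.15, adjusted p = 0.303). By camera the adjusted p was 1.7e-06, and the adjusted p was 0.131 with an estimated correlation.

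**Figure D4:**
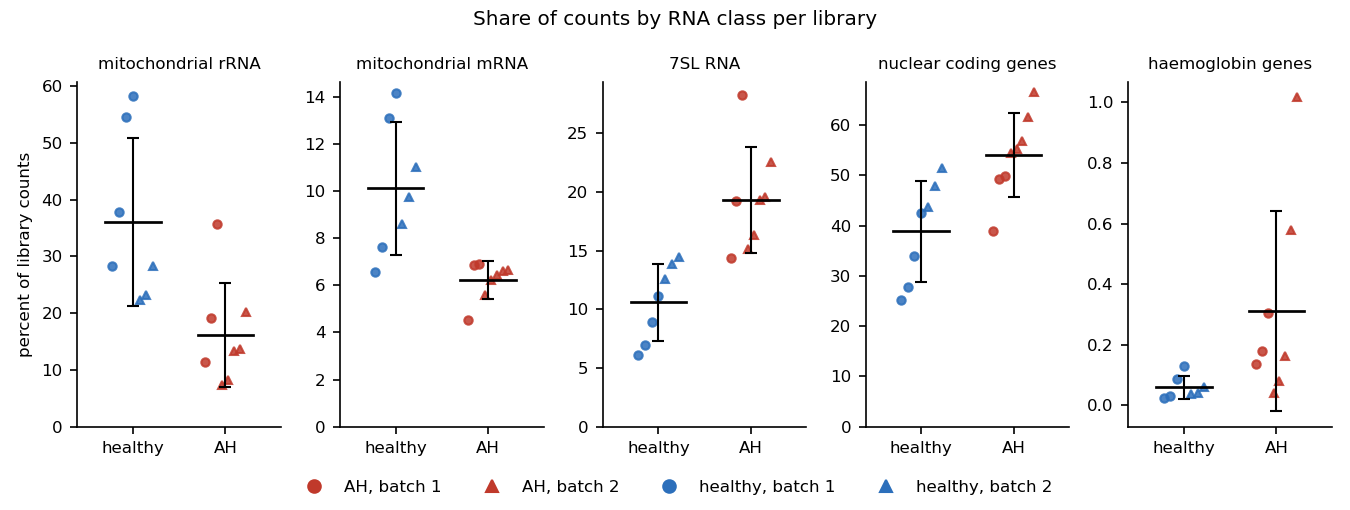
Percent of each library's counts (vertical axes) from mitochondrial rRNA, mitochondrial mRNA, 7SL RNA, nuclear protein-coding genes and haemoglobin genes in 7 healthy and 8 AH libraries, with circles for batch 1, triangles for batch 2, and lines and bars for mean and SD. Mitochondrial rRNA averages 36.1% in healthy donors and 16.1% in AH.

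Cytosolic ribosomal protein genes had a median of -0.48 over 76 genes, 4 of them positive. The list's camera adjusted p was 1.6e-07, but the adjusted p was 0.512 with an estimated correlation and 0.0809 with fry. Few single members passed: 5 fell, including RPL3 (-0.69, SE 0.22), RPS23 (-0.74, SE 0.24), RPL10A (-0.78, SE 0.25) and RPL34 (-0.70, SE 0.23), and 0 adjusted over the list alone. The calls of these 4 genes were each lost in 12 to 14 of 15 fits that left out 1 library, and for each of them 1 batch 1 AH library was highest and stood apart from the other AH libraries. Though 17 members fell with GC and length offsets and RPL3 reached -1.05 (SE 0.23), RPS23 (adjusted p = 0.0994) and RPL34 (adjusted p = 0.208) did not pass. The many pseudogenes of ribosomal protein genes share reads with them. Of 19 endoplasmic reticulum stress genes, 5 rose and 1 fell (also adjusted over the list alone). The chaperones CALR (1.10, SE 0.21) and CANX (0.64, SE 0.15) and the transcription factor ATF4 (1.03, SE 0.24) rose. ATF4 became 0.68 (SE 0.21) with GC and length offsets. ATF3 fell by 0.77 (SE 0.21), a call lost in 5 of 15 fits with 1 library left out. By camera the list did not pass (adjusted p = 0.088, and 0.359 with an estimated correlation). It passed with fry (adjusted p = 0.0359) and by camera with GC and length offsets (adjusted p = 0.020). Of 18 proliferation genes, 4 rose (5 adjusted over the list alone), with medians of 0.44 in batch 1 and 0.83 in batch 2. They were MKI67 (1.07, SE 0.28), TPX2 (0.94, SE 0.25), BUB1 (0.61, SE 0.18) and BIRC5 (1.52, SE 0.51). BIRC5 had an adjusted p of 0.105 with GC and length offsets, and its call was lost in 9 of 15 fits with 1 library left out. The list's camera adjusted p was 0.0148, but the adjusted p was 0.404 with an estimated correlation and 0.0809 with fry. None of 20 apoptosis regulators passed (0 adjusted over the list alone): CASP8 had a log2 fold change of -0.58 (SE 0.21), BIRC3 -1.19 (SE 0.44), PMAIP1 -0.86 (SE 0.34) and CASP9 0.57 (SE 0.24), and the camera adjusted p was 0.459. With fry the apoptosis list was lower (adjusted p = 0.0425). Of 12 nuclear and structural noncoding RNAs, RN7SL1 and RN7SL2, the near-identical copies of the signal recognition particle RNA, rose (0.87, SE 0.23, and 0.66, SE 0.22) and GAS5 fell by 0.79 (SE 0.22), the same calls as adjusted over the list alone, MALAT1 had -0.68 (SE 0.41), and the list did not pass (camera adjusted p = 0.459). GAS5 (adjusted p = 0.170) and RN7SL2 (adjusted p = 0.0768) did not pass with GC and length offsets, and they lost their calls in 4 and 2 of 15 fits with 1 library left out.

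The contrast was repeated in each batch on separate people. Batch 1 called 76 genes higher and 8 lower among 13672, and batch 2 called 327 higher and 144 lower among 13450. Of the genes tested in both, 42 were called higher in both against 1.88 expected for independent lists, 4 were called lower in both against 0.0772 expected, and 0 were called in opposite directions. Of 83 genes called in batch 1 and tested in both, 82 had the same sign in batch 2, and 445 of 460 genes called in batch 2 had the same sign in batch 1. Fold changes correlated across 12882 genes, which are not independent replicates (Pearson's r = 0.471, Spearman's rho = 0.534). For differences of mean log2 CPM, r was 0.508, which none of the other relabelings within batches reached (highest 0.478). The interaction test in edgeR called 0 genes, with 520 at an unadjusted p under 0.05, and DESeq2 called 2. Both counts within batches rest on few libraries, since leaving out 1 library gave 0 to 44 genes in batch 1 and 4 to 551 in batch 2.

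**Figure D5:**
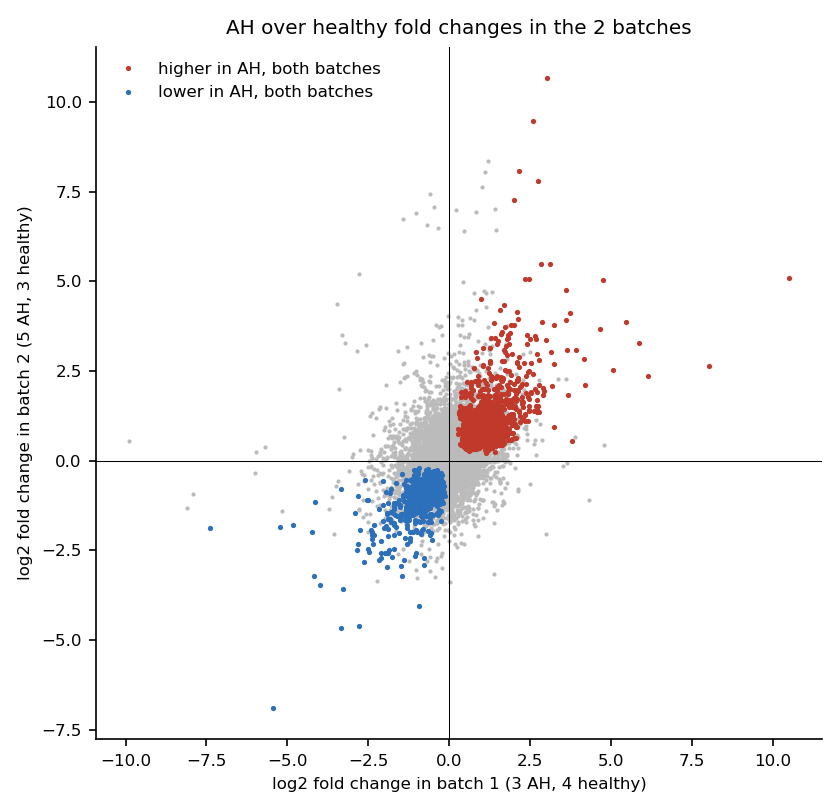
Log2 fold changes of AH over healthy in batch 1 (horizontal axis, 3 AH and 4 healthy libraries) and batch 2 (vertical axis, 5 AH and 3 healthy libraries), one point per gene; genes called with both batches together are red (higher) or blue (lower). The called genes lie in the quadrants where both batches have the same sign, which their selection on both batches together largely ensures.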

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

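The tests in this part other than those of other splits were chosen after the results they bear on were seen, although the bounds for GC content and mitochondrial share were written before those fits were run, and the permutation test of the ZNF genes with offsets was added after their median was seen.

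S100A8, S100A9 and S100A12 together averaged 1.63 higher on the log2 scale in AH (exact permutation p = 0.023). More mature neutrophils or monocytes would raise their own markers as well. The mean levels of those markers differed by 0.146 and -0.149 (exact permutation p = 0.705 and 0.742), so no rise of either was seen. The S100 mean rose by 1.48 more than the mature neutrophil markers and by 1.78 more than the monocyte markers (exact permutation p = 0.0051 for each). Both comparisons were chosen after the values were seen, so their outcome was largely set. They do not decide the source, since the amount of S100 RNA per cell is not known. CSF3R and FCGR3B, abundant in neutrophils, had log2 fold changes of 0.30 (SE 0.48) and 0.24 (SE 0.56), and LYZ, abundant in monocytes, 0.35 (SE 0.40). Granule protein genes, made mainly by immature granulocytes, had positive fold changes in 13 of 13 tested, of which 5 passed, and the S100 mean minus their mean differed by -0.35 (exact permutation p = 0.345), so RNA of immature granulocytes may be a source, with MPO at 4.96 CPM in AH. A change within platelets or megakaryocytes of AH patients was not tested apart from this and stays open.

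Of 24 tested erythroid genes 15 rose in AH. Positive fold changes were found in 95.8% (23), all 8 haemoglobin genes included, as red cell or reticulocyte carryover would give. This measure was chosen after the rise was seen and restates it, so it does not test carryover. The list's adjusted p was 0.190 with an estimated correlation. A lower share of platelet RNA would raise all other cell types alike. The erythroid mean rose by 2.63 more than the T and NK cell markers (exact permutation p = 0.00051, the smallest possible). That comparison was chosen after those markers were seen to be lower, so its outcome was largely set. On the log2 scale the erythroid mean differed by 1.94, the neutrophil granule mean by 1.98 and the T and NK cell mean by -0.69. The B and plasma cell mean differed by -0.99, so cell types did not move alike. A lower platelet share would also lower the platelet identity markers. Their mean was instead higher in AH by 0.54 (exact permutation p = 0.00867, adjusted p = 0.0282). These values argue against a lower platelet share as the source of the erythroid rise. The platelet marker mean of healthy donors was lowest in batch 1, however, where their mitochondrial rRNA share was highest. A GC and length trend is not the whole source, since the list's median stayed at 1.89 with offsets for both. Carryover may account for these rises but was not tested apart from them. A change in megakaryocytes or in red cell production in AH cannot be excluded, since ANK1, DMTN and others of these genes are also expressed in platelets.

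The 2190 called genes as a whole were GC-rich when higher and GC-poor when lower (rho 0.314 between fold change and GC over 12782 genes, which are not independent). With GC and length offsets, 59.7% were called again with the same sign, and the relation turned to rho = -0.14, so the offsets removed more than the trend. Without mitochondrial genes and without the 2 healthy libraries over 50% mitochondrial rRNA, 57.6% were called again. Both shares lie between the bounds, which were written after the calls were seen but before these fits were run, and the second fit also has fewer libraries, so these technical sources and a difference between AH and healthy platelets cannot be told apart for the calls as a whole. The 401 ZNF genes kept a median of -0.35 with offsets, against -0.39 without (exact permutation p = 0.00459 for their mean with offsets), which argues against GC and length as the whole source for them.

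Chance in how the libraries fall into groups is an unlikely source of the called genes, but the few splits compared cannot exclude it. With both batches, 100 of 1960 possible splits were drawn. The real split was the only 1 of 100 splits within batches to reach 2190 genes, and the highest other split called 0. In batch 1, 1 of 35 splits reached 84 genes (highest other 3), and in batch 2, 1 of 56 splits reached 471 (highest other 4). For gene lists, 4 of 100 splits gave 16 or more called lists, and the highest other gave 19, so a count of 16 lists by the preset correlation is rare but not the most that these libraries can give. The interaction called 0 genes, a count that all 100 splits reach whatever the data (highest other 2), so the splits say nothing about it.

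In 16 of 244 groups of values, 1 library stood far from the rest of its group; chance gives about 1 in 20. The gap to the nearest library, as a share of the group's range, is given for each, and the library need not be the same from gene to gene. In AH, 1 batch 1 library was lowest for ALB (0.619), CFL1 (0.571) and FCGR2A (0.669), and 1 was highest for RPL3 (0.594), RPL10A (0.744), RPL34 (0.596), RPS23 (0.590) and the mitochondrial rRNA share (0.544). In batch 2, 1 AH library was highest for IFI6 (0.584). Among healthy donors, 1 batch 1 library was lowest for BIRC5 (0.807), IGFBP2 (0.586) and MYL9 (0.653) and 1 was highest for NKG7 (0.579). In batch 2, 1 healthy library was highest for LAMP5 (0.577) and 1 was lowest for S100A8 (0.632) and S100A9 (0.705).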

How the results depend on the processing

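Alternatives added after seeing the data are GC and length offsets, nuclear protein-coding genes only, leaving out the 2 healthy libraries over 50% mitochondrial rRNA, leaving out the AH library apart on the third component, and the erythroid covariate. For 108 named genes other than S100A9, all past the threshold in the main fit, 3923 comparisons were made under alternatives. A gained call could therefore not appear. Of these comparisons, 3247 gave the same direction and side of the threshold, 674 the same direction but no longer past it, and 2 changed sign. Both were with the erythroid covariate: ALAS2 had a log2 fold change of -0.65 and BLVRB -0.29. The mean of the erythroid list ran from 3.12 to 5.83 in AH and from 1.78 to 3.44 in healthy donors, so the covariate nearly follows the groups, and it left 20 genes higher and 1 lower, with 12 and 4 lists. Leaving out 1 library ended the call of 28 of the 108 named genes in at least 1 fit. Total counts averaged 38.8 M in AH and 39.0 M in healthy donors, and simulated data show that most 1.5-fold changes could not be detected.

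The counts of 1226 higher and 964 lower genes became 608 and 572 with the lymphocyte covariate, 598 and 280 with a fold of at least 2, 76 and 8 in batch 1 only and 327 and 144 in batch 2 only, where fewer libraries were tested. Genes lower in AH became 542 with library sizes alone and 443 without the libraries over 50% mitochondrial rRNA. Leaving out each library gave 1022 to 1409 higher and 510 to 898 lower genes. The lower count moved by over 1.5 times without any 1 of 4 healthy libraries, 1 in batch 1 and 3 in batch 2 (593, 571, 510 and 586). The cause was not tested.

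S100A9 kept its direction under all alternatives. It passed the threshold with DESeq2 (1.55, adjusted p = 0.0414), with no filter (1.55, adjusted p = 0.0017), with the neutrophil and monocyte covariate (1.49, adjusted p = 0.0348) and without the AH library apart on the third component (1.83, adjusted p = 0.0391). With the lymphocyte covariate it was 0.81 (SE 0.68, adjusted p = 0.542). Over the single libraries left out it ranged from 1.20 to 1.83, and its adjusted p over all alternatives from 0.0017 to 0.542. The cause was not tested.

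The replicate numbers 1 to 3 are shared by batch 1 libraries of different people, so the libraries were treated as unpaired. Deviations of same-numbered libraries correlated at -0.06 to 0.19, over 0.1 in 2 of 3 pairs, and those of differently numbered ones at -0.18 to 0.0725. Of the AH libraries, 2 of 3 correlated best with their own number. With 3 pairs, something shared by number cannot be excluded. With the numbers as a replicate block in these 6 libraries, 0 genes were higher and 0 lower, S100A9 had a log2 fold change of 0.59, and 11 lists were higher and 4 lower; the fit has fewer libraries.

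In batch 1, 84 genes became 993 with DESeq2, 24 with library sizes alone, 297 with the strict filter and 0 to 44 with each library left out. In batch 2, 471 became 1449 with DESeq2, 909 with the strict filter and 4 to 551 with each library left out. The correlation of 0.471 between batches became 0.781 with the strict filter, which keeps highly expressed genes, and ranged from 0.296 to 0.527 over libraries left out. The 0 interaction genes became 2 with DESeq2 and 0 to 1 with libraries left out. The 12 lists higher and 4 lower became 0 and 0 with an estimated correlation and 13 and 4 with fry, not all of them the same lists. With each library left out they became 10 to 14 and 4. Of 13 composition measures, 5 passed, and 8 of 11 passed with shares without mitochondrial genes. There only the haemoglobin share and the share of the 10 largest genes were computed anew. The marker means were unchanged, so those that newly passed did so through the adjustment over 11 measures. In batch 1 only and in batch 2 only 0 passed, where p cannot fall under 0.0286 and 0.0179, and 1 to 10 passed with each library left out. For the other changes the cause was not tested.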

Other observations

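Zinc finger genes named ZNF were lower as a group in AH platelets. Of 401 tested, 45 fell and 11 rose, with a median log2 fold change of -0.39, and their mean log2 CPM was 0.258 ± 0.176 in AH and 0.707 ± 0.189 in healthy donors (exact permutation p = 0.00102, chosen after the values were seen). The difference was -0.50 in batch 1 and -0.33 in batch 2.

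Of 355 antisense genes tested, 37 fell and 7 rose, and of 314 long intergenic RNAs, 28 fell and 9 rose, whereas of 20 sense-overlapping genes 4 rose and 0 fell and of 111 processed transcripts 6 rose and 7 fell. Among 11290 protein-coding genes 1160 rose and 825 fell. Of 22 mitochondrial tRNAs, 12 fell and 0 rose, in the same direction as the mitochondrial mRNAs. The signal recognition particle RNAs took 19.4 ± 4.52% of counts in AH and 10.6 ± 3.32% in healthy donors (exact permutation p = 0.00051, the smallest possible), and nuclear protein-coding genes 54.1 ± 8.36% and 38.9 ± 10.1% (exact permutation p = 0.00306). Without known strand handling, antisense genes can hold reads of their partners.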
